A study of Mus musculus with 6 samples.

How the data were processed

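Total RNA from mouse skeletal muscle was measured on 6 spotted arrays with 2 channels each. Per the labels, channel 1 held the muscle sample and channel 2 held one reference RNA from control muscle, called Pre. Each group had 1 array: a sham group with an implanted but inactive pacer, and groups harvested 0 h, 1 h, 3 h, 8 h and 24 h after 3 h of electrical pacing. The sham muscle was taken at the time that matched 0 h. At 1 h, 3 h, 8 h and 24 h a difference from sham therefore mixes pacing with elapsed time. The number of mice behind each RNA was not stated, and with 1 array per group there was no replicate check, so no p-value was computed.

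The deposited table holds 1 log10 ratio per probe and array for 13872 probes, with no signals or quality marks. The log base is not stated per the labels; it was read from 97 cells that hold the rounding residue 9.64e-17, the log10 of 1 plus the smallest floating-point step. The scanner, image analysis, background correction and normalisation were not given in the sources used here. Probes in ID order fell into 48 runs of 289, and the median was exactly 0 in 48 of them at 0 h, 46 at 24 h, 43 at 3 h, 39 at 1 h, 17 at 8 h and 6 in sham. Run medians were at most 0.10 in log2 units in size, on the sham array. Exact zeros were included in these medians, and they numbered 1762 at 0 h and 201 in sham. Many zeros in a run can make its median exactly 0. Whether the ratios were centred per run (print block) therefore cannot be told for any array. The ratio is likely sample over Pre, because the labels name Pre as the reference, but the dyes are not stated. All directions below rest on that reading. All 15 pairs of arrays correlated positively across genes (genes are not independent replicates), with r from 0.22 to 0.75, so no array stood the opposite way to the others.

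Exact zeros on the paced arrays, from 665 at 8 h to 1762 at 0 h, were treated as fill-ins for spots that were not measured. At 24 h, 5.61% of genes' other probes were 2-fold from Pre where a sibling probe stood at 0, close to 5.30% of all genes. At 0 h the shares were 0.820% and 2.11%, so some zeros there could be measured values. The shares were 1.15% and 0.770% at 1 h, 4.67% and 5.37% at 3 h, and 1.87% and 2.22% at 8 h. The first share covers genes with several probes and the second all genes, so the comparison cannot decide what the zeros are. The sham array differed in form, with 485 empty cells, 201 zeros and 154 values shared within a print block. It may have been processed differently, which the sources used here do not state. If so, every comparison with sham also carries that difference. Zeros and shared values were set to missing. The share of probes left was 93.9% for sham, 87.3% at 0 h, 90.9% at 1 h, 87.9% at 3 h, 95.2% at 8 h and 87.7% at 24 h. The handling of zeros and shared values was decided after the values had been seen, and the alternative kept them.

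The log10 ratios were converted to log2, and each array was centred on the median of its measured probes. The medians removed were largest in size at 8 h, at -0.01. Robust standard deviations (SD) of the log2 ratios were 0.495 for sham, 0.292 at 0 h, 0.176 at 1 h, 0.445 at 3 h, 0.242 at 8 h and 0.400 at 24 h. Precision is limited by the number of arrays.

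Probe names came from the platform annotation. Exactly 1 gene symbol was given for 6609 probes, several for 284 and none for 6979. Of the 6609, 6599 matched the GRCm38.p6 gene table by Entrez ID; that table served for names alone. A gene's value was the mean of its measured probes with exactly 1 symbol, and the probe SD quoted beside a gene is the spread of the probes' differences, not of animals, over the probes measured on both arrays, whose number is given with it. Genes with a value on all 6 arrays numbered 3180 of 3939, of which 1127 had several probes and 2053 had 1. A gene named as highest or lowest at a time without a probe count or probe SD had 1 probe, so no second probe checks it. Because different probes of a gene can be missing on different arrays, an alternative kept probes measured on both arrays of a comparison. cDNA spots can bind close relatives, so Mt1, Actg2, Amd2, Ubb-ps, the ribosomal protein genes and the myosin genes are uncertain as to the family member.

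Each paced array was compared with sham by subtracting the log2 ratios, and a gene was called at 2-fold, an absolute log2 difference of 1 or more. The sham array had the largest robust SD, though the plain SD was larger at 3 h (0.547) and 24 h (0.544) than in sham (0.529), and a difference from sham also carries the deviations of that array. Genes were therefore also counted when they were 2-fold from both sham and Pre in 1 direction. Both comparisons use the same paced value, so an error in that value counts in both. That double condition was part of the naming rule fixed before the data were examined; its use as a count beside the main one was added later. The rule named, for each time, up to 10 genes highest and 10 lowest against sham among those that met the double condition. It added genes that met it at 3 or more of the 5 times, the 5 highest and 5 lowest genes of sham against Pre, and, from each fixed list, members that met it plus up to 4 others with the largest difference.

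The 25 gene lists were fixed from textbook knowledge before the data were examined. Some genes were on more than 1 list, such as Eno3 (glycolysis and fast fibre), Mt1 (atrophy and antioxidant) and Csrp3 (slow fibre and myogenic). The lists are therefore not separate evidence for such genes. Measured members numbered 17 of 36 immediate early, 19 of 29 heat shock and chaperone, 15 of 26 exercise-responsive metabolic regulator, 17 of 21 glycolysis and glycogen, 51 of 58 oxidative phosphorylation and TCA cycle, 15 of 17 fast fibre, 18 of 19 slow fibre, 10 of 25 atrophy and proteolysis, 21 of 31 proteasome, 50 of 71 ribosomal protein, 13 of 26 antioxidant and metallothionein, 5 of 35 cytokine and acute phase, 17 of 37 extracellular matrix, 5 of 26 myogenic, 4 of 19 circadian, 6 of 25 angiogenic and hypoxia, 5 of 26 interferon and 12 of 26 cell cycle genes. Marker lists had 5 of 27 macrophage and neutrophil, 1 of 18 lymphocyte, 1 of 12 erythroid, 4 of 13 adipocyte, 8 of 16 endothelial and smooth muscle, 0 of 13 Schwann cell and 1 of 11 keratinocyte genes. For lists with at least 5 measured members, the median was placed among 10000 random lists of the same size. These were not matched on expression, since the table has no signals, and the counts describe these arrays alone.

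The calling step was tested on simulated data built from the arrays' spreads with 200 changed genes. At 24 h against sham, with 3180 genes, a true 2-fold change was found for 49.3% of 67 genes by the comparison with sham and for 40.3% by the double condition. That simulated change equals the threshold, so the rate against sham is near an even split by design and does not measure sensitivity. The rates were 94.0% and 94.0% for 67 genes changed by 2 log2 units. Of 2980 unchanged genes, 10.8% were called against sham and 0.772% by the double condition at 24 h. At 3 h these shares were 13.5% and 1.34%, at 0 h 8.19% and 0.0336%, at 1 h 5.40% and 0%, and at 8 h 6.78% and 0%. The simulated arrays varied independently, which the real ones did not. Each simulated gene also had a normal spread set by the robust SD of probes, though many real genes are means of several probes. The plain SD was larger than the robust SD, at 0.283 against 0.176 at 1 h and 0.385 against 0.242 at 8 h. The 0% at these times may therefore be too low. At each time, more unchanged genes were called against sham in simulation than genes of any kind on the real arrays. The shares therefore do not give the rate of false calls on the real arrays.

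Alternatives were the values as deposited, arrays scaled to 1 median absolute deviation, probes counted one by one, genes measured on the arrays compared, a 1.5-fold threshold, a threshold of 3 robust SDs of sham, Pre in place of sham, the median of probes and the mean of list members. Keeping zeros and shared values, and keeping probes measured on both arrays, were added after the data had been seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.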

Results

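Transcript levels were measured in mouse skeletal muscle from 6 groups with 1 array each: sham-operated muscle, and muscle taken 0 h, 1 h, 3 h, 8 h and 24 h after the end of 3 h of electrical pacing through an implanted pacer. Each array set its sample against the same reference RNA, Pre, from control muscle. Values were log2 ratios for 3180 genes with a value on all 6 arrays; no signal levels were given. Because every group had 1 array, the differences below have no replicate check, and the directions take the likely reading of the ratio as sample over Pre. Sham was matched in time to 0 h alone, so differences from sham at later times mix pacing with elapsed time.

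Sham against Pre set operated muscle with an inactive pacer against the control reference, without stimulation. On the sham array the highest named genes were Actg2, a smooth muscle actin, at a log2 ratio to Pre of 2.52, Rgcc, a cell cycle regulator, at 2.51, and Mlycd, malonyl-CoA decarboxylase, at 2.15. Ppp1r3c, which targets a phosphatase to glycogen, stood at 2.11 (2 probes, probe SD 0.01) and Ift20 at 2.09. The lowest were Abhd10 at -2.11, H2bc4 at -1.59, Pygb, a glycogen phosphorylase, at -1.59, Hps4 at -1.53 and Rhd at -1.52. In all, 58 genes (54.7%) were at least 2-fold higher and 48 at least 2-fold lower than Pre; with arrays scaled to a common spread these were 20 (71.4%) and 8.

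Gene groups also stood away from Pre in sham muscle. The median of the 51 oxidative phosphorylation and TCA cycle genes was 0.28, with 46 members above Pre, and that of the 50 ribosomal protein genes was 0.28, with 42 above. For both lists, 0 of 10000 random lists had a median as high. The 10 atrophy and proteolysis genes had a median of 0.59, with the ubiquitin ligase genes Trim63 at 1.61 and Fbxo32 at 1.37. The 21 proteasome genes had a median of 0.31, and 19 of 10000 random lists were as high. The 15 exercise-responsive metabolic regulators had a median of 0.33, with Pdk4, a kinase that restrains pyruvate oxidation, at 1.89. The 17 extracellular matrix genes had a median of -0.27, with 13 below Pre.

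Immediately after pacing (0 h against sham), Sik1, a salt-inducible kinase gene, was 5.57-fold higher than in sham, with log2 ratios to Pre of 1.44 at 0 h and -1.03 in sham. Mt1, a metal-binding metallothionein, was 4.72-fold higher, and Pdk4 was 3.15-fold higher (3 probes, probe SD 0.46 in log2 units). Fbxo32 was 2.97-fold higher, Lrrc58 3.73-fold, Plcb4 3.72-fold, Slc20a1 2.74-fold (2.27-fold on the 2 probes measured on both arrays, probe SD 0.70), Arcn1 2.69-fold, Txnl1 2.53-fold (2 probes, probe SD 0.11) and the acute phase gene Serpina3n 2.45-fold. Among genes that were also 2-fold below Pre, Golga1, which codes for a Golgi protein, had the largest decrease from sham, a log2 difference of -2.56. Actg2, high in sham, differed by more, -3.41, but stood at -0.89 against Pre. It was followed by Nav2 at -1.87, Lrpprc, which binds mitochondrial RNA, at -1.83, 1810037I17Rik at -1.61, Plaat1 at -1.43 and Aqp4, the water channel of fast fibres, at -1.39 (2 probes, probe SD 0.01). Fam219b at -1.36, Prkag3, a muscle subunit of the AMP-activated kinase, at -1.30 and Ppic at -1.18 completed those lower than both references.

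At 0 h, 2 of the 17 immediate early genes met the double condition, Sik1 and Btg2. The list median was 0.12 against sham, with 3134 of 10000 random lists as high, and 0.15 against Pre, with 244 as high. The mean of Btg2 was 2.12-fold that of sham, but its 2 probes disagreed, with a probe SD of 2.07. Among chaperones, Dnajb1, which assists Hsp70, was 2.42-fold higher and Hspe1 stood at -1.14 against sham and -0.20 against Pre; the list median was 0.14. The 10 atrophy and proteolysis genes had a median of 0.73, with 9 above sham, and 2 of 10000 random lists reached it; Trim63 stood at 0.87 and Gabarapl1 at 0.78. The 17 glycolysis and glycogen genes had a median of -0.33, with 13 below sham, and 55 of 10000 random lists were as low; against Pre it was -0.20. Oxidative phosphorylation and TCA cycle genes had a median of -0.33 against sham but -0.04 against Pre, the sham array itself lying above Pre. Fast fibre genes had a median of -0.17 against sham, with 12 of 15 below it. Myh4, a fast myosin gene, went the other way, at 0.87 on the 33 probes measured on both arrays (probe SD 0.81). Its gene mean was 0.21 against Pre, with sham at -0.57. Rcan1, a calcineurin inhibitor, stood at 1.12 against sham (2 probes, probe SD 0.09) and 0.90 against Pre.

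In total 99 genes were at least 2-fold higher and 91 lower at 0 h than in sham. Of these 190 genes, 164 were not 2-fold from Pre in the same direction, while 17 higher and 9 lower genes met both conditions. Against Pre alone, 69 genes were called. With arrays scaled to a common spread, 67 genes met both conditions.

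At 1 h after pacing, Lrrc58 was 2.57-fold higher than sham, at a log2 ratio to Pre of 1.81. Retreg1, a receptor for autophagy of the endoplasmic reticulum, was 2.91-fold higher as the mean of its probes, yet the log2 difference was 0.75 on the 1 probe measured on both arrays, below the threshold. Sik1 was 3.60-fold higher than sham but at 0.81 against Pre. Mt1 stood at -0.42 against sham, and the atrophy and proteolysis list at -0.02. With arrays scaled to a common spread those values were 0.30 and 0.85. Against Pre the list median was 0.59, as in sham, with 10 of 10 members above Pre and 0 of 10000 random lists as high. Txnl1 stood at 0.94 (probe SD 0.22).

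The 15 fast fibre genes had a median of -0.22 at 1 h against sham, with 13 below it, and 151 of 10000 random lists were as low. It was -0.11 against Pre, with 8 of 15 below, and -0.44 against sham after scaling. Heat shock and chaperone genes had a median of 0.03 against sham and 0.16 against Pre; 2 of 10000 random lists were as high against Pre. Ribosomal protein genes had a median of -0.20 against sham and 0.10 against Pre. At 1 h, 25 genes were at least 2-fold higher and 17 lower than sham, and 2 higher and 0 lower genes met both conditions. Against Pre alone 27 genes were called. The ratios of this array had the smallest spread of the 6, a robust SD of 0.176, and scaling to a common spread gave 55 genes that met both conditions, 44 higher (80.0%) and 11 lower, against 2 higher (100%) and 0 lower in the main count.

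At 3 h after pacing, Sik1 was 12.5-fold higher than sham, its largest difference in the series, at a log2 ratio to Pre of 2.61. 2310039H08Rik was 5.06-fold higher, Lrrc58 3.27-fold, Chrd, a bone morphogenetic protein antagonist, 2.83-fold, and Rgcc 2.74-fold. Txnl1 was 2.56-fold higher (probe SD 0.23), Rassf1 2.52-fold, Nop14 2.52-fold and Sf3b2, a splicing factor, 2.36-fold. Rassf1, Nop14 and Sf3b2 had 1 probe each. Against Pre, Sf3b2 stood between -0.06 and 0.25 on the other paced arrays, while Rassf1 stood at 0.28 or more and Nop14 at 0.54 or more. Of genes that were also 2-fold below Pre, Ap1m1, a clathrin adaptor subunit, was lowest at -2.34, followed by Golga1 at -2.00, Pdgfra, the platelet-derived growth factor receptor of fibroblasts, at -1.59, the splicing regulator Tra2a at -1.26 and 2310065F04Rik at -1.05. Rab5c at 1.32 and Efna5 at -1.03 met both conditions as means of 2 probes, but stood at 0.87 and -0.53 on the probe measured on both arrays.

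Of the 17 immediate early genes, 3 met both conditions at 3 h: Sik1, Rrad, a small GTPase, at 1.01, and Btg2, 2.01-fold higher with a probe SD of 1.58. The list median was 0.03 against sham, with 7 members below sham and 4396 of 10000 random lists as high. Mt1 was level with sham, at -0.01, and Mlycd was lower at -2.07, with a log2 ratio to Pre of 0.08 against 2.15 in sham. Fast fibre genes had a median of -0.24, with 12 of 15 below sham, and 61 of 10000 random lists were as low. Atrophy and proteolysis genes had a median of 0.15 against sham and 0.86 against Pre, with 9 of 10 above Pre and 0 of 10000 random lists as high on that basis. At this time 42 genes were at least 2-fold higher and 26 lower than sham, and 20 higher (76.9%) and 6 lower genes met both conditions; scaling to a common spread left 9 higher (100%) and 0 lower. Against Pre alone 158 genes were called. In simulated arrays that varied independently, 1.34% of 2980 unchanged genes met both conditions at 3 h, a number above the 26 genes called here. The same simulation called 13.5% of unchanged genes against sham at 3 h, far above the 68 genes called on the real arrays. It overstates false calls there, so it cannot say how many of the 26 genes are false calls.

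At 8 h after pacing, Mt1 was 4.84-fold higher than sham, Sik1 4.57-fold and Serpina3n 3.05-fold. Ankrd1, a stretch-responsive repeat protein of the sarcomere and nucleus, was 2.91-fold higher (3 probes, probe SD 1.57). As3mt was 2.65-fold higher, Txnl1 2.35-fold (probe SD 0.21), Anapc16 2.28-fold, 2310057M21Rik 2.20-fold, Sat1, which acetylates polyamines, 2.18-fold and Lrrc58 2.14-fold. The lowest genes that were also 2-fold below Pre were Klhl34 at -1.80, Plaat1 at -1.55, Syt4 at -1.43, Aqp4 at -1.39 (probe SD 0.43), Snap91 at -1.37 and Prkag3 at -1.37. Tfrc, the transferrin receptor, stood at -1.14 (2 probes, probe SD 0.05), Klhl31 at -1.14 and Amd2 at -1.12 (2 probes, probe SD 0.24).

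Glycolysis and glycogen genes had a median of -0.46 at 8 h, with 15 of 17 below sham and 2 of 10000 random lists as low; against Pre the median was -0.18. Heat shock and chaperone genes had a median of 0.34, with 13 of 19 above sham and 75 of 10000 random lists as high. The atrophy and proteolysis median was 0.62 against sham, 1.14 against Pre and 1.16 against sham after scaling, with 9 of 10 above sham and 0 of 10000 random lists as high; Mt1 was the 1 member that met both conditions. Txnip, a thioredoxin-binding protein, stood at -0.93 against sham (2 probes, probe SD 0.11) but at 0.25 against Pre, with sham itself at 1.17; scaling gave -0.46 against sham. In total 53 genes were at least 2-fold higher and 50 lower, and 10 higher and 9 lower met both conditions. Against Pre alone 75 genes were called, and scaling to a common spread gave 86 that met both conditions.

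At 24 h after pacing 39 higher and 26 lower genes met both conditions, the most of the 5 times in the main count; with arrays scaled to a common spread there were 38, against 86 at 8 h. Ankrd1 was 8.07-fold higher than sham as a mean of 3 probes that disagreed (probe SD 2.29): log2 ratios to Pre were 4.15 and 3.94 on 2 probes and 0.89 on the other. Mt1 was 6.52-fold higher, Sik1 4.27-fold, Rprd1b 3.89-fold, Txnl1 3.36-fold (probe SD 0.25), 2310057M21Rik 3.21-fold and Fbxo32 3.12-fold. Myl12b, a regulatory myosin light chain, was 3.19-fold higher (5 probes, probe SD 1.29), and its log2 difference of 1.67 was 0.96 with zeros and shared values kept. Odc1, the first enzyme of polyamine synthesis, was 2.94-fold higher (2 probes, probe SD 0.79).

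Heat shock and chaperone genes had a median of 0.65 at 24 h against sham and 0.82 against Pre, with 15 of 19 above sham and 0 of 10000 random lists as high on either basis. The small heat shock protein genes Hspb7, 3.11-fold higher (5 probes, probe SD 0.90), and Hspb8, 2.58-fold, and the constitutive Hsp70 gene Hspa8, 2.01-fold (11 probes, probe SD 0.25), met both conditions. Hsp90aa1 stood at 0.95 (5 probes, probe SD 0.77) and Hsp90b1 at 0.86 (3 probes, probe SD 0.30). The atrophy and proteolysis median was 0.54 against sham, with 10 of 10 above it, and 1.25 against Pre. Ribosomal protein genes had a median of 0.20 against sham and 0.51 against Pre, with 39 of 50 above sham and 470 of 10000 random lists as high. The proteasome median was 0.16 against sham, with 16 of 21 members above sham and 2297 of 10000 random lists as high. Against Pre it was 0.64, with 0 of 10000 as high. Psma3, 2.28-fold higher, met both conditions. In the other direction, 1 member was at least 2-fold lower than sham, and Psmc5 stood at -0.47 against Pre, with sham at 0.93.

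Glycolysis and glycogen genes had a median of -0.53 at 24 h against sham and -0.34 against Pre, with 15 of 17 below sham and 0 of 10000 random lists as low; Pfkm, muscle phosphofructokinase, stood at -1.04 against sham on the 5 probes measured on both arrays (probe SD 0.46), Eno3, muscle enolase, at -1.04 (2 probes, probe SD 0.19) and Ldha at -0.76 on 10 such probes (probe SD 0.43). With arrays scaled to a common spread the list median was -0.37. Fast fibre genes had a median of -0.30, with 10 of 15 below sham, 5 above and 58 of 10000 random lists as low. The 2 members that met both conditions were Casq1 and Eno3, which is also on the glycolysis list. Casq1, the calcium store protein, stood at -1.04 (9 probes, probe SD 0.82). Atp2a1, the calcium pump, was 1 of the 5 above, at 0.58 on the 4 probes measured on both arrays (probe SD 0.36). Slow fibre genes had a median of -0.02 against sham and -0.25 against Pre, with 16 of 18 below Pre; the fast fibre median against Pre was also -0.25. The lowest genes that were also 2-fold below Pre were Patj at -1.95, Plaat1 at -1.87, Anxa1 at -1.78, Celsr2 at -1.74, Klhl31 at -1.71, Gpr153 at -1.71, Tcap, a Z-disc cap of titin, at -1.61 (4 probes, probe SD 0.27), Tmem233 at -1.58, Grb14, an insulin receptor adaptor, at -1.56 and Mlf1 at -1.51 from gene means, but -1.20 on the 2 probes measured on both arrays (probe SD 0.08).

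Against sham alone, 96 genes were at least 2-fold higher and 89 lower at 24 h, and 120 of the 185 were not 2-fold from Pre in the same direction. Against Pre alone 172 genes were called.

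**Figure D1:**
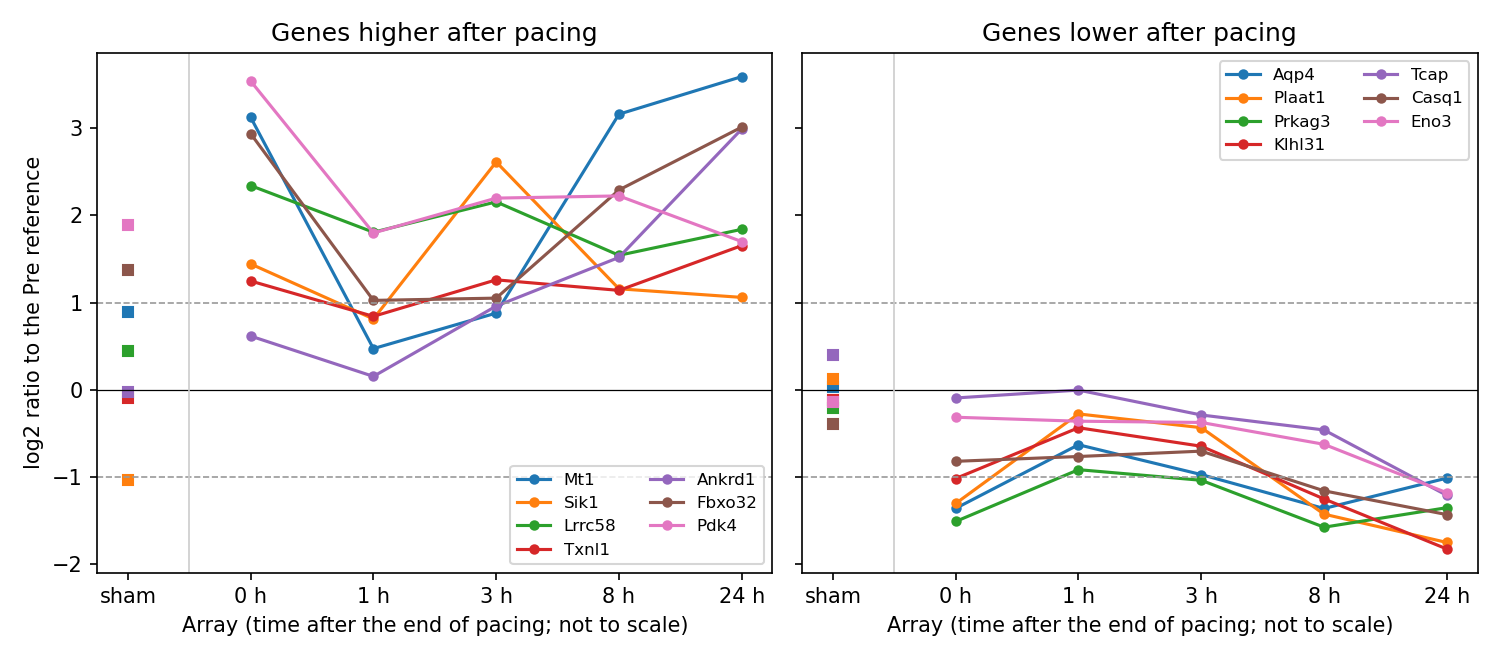
Log2 ratio to the Pre reference (vertical axis) by array (horizontal axis, times not to scale). The 7 genes at left met both conditions in the higher direction, and the 7 at right in the lower, at 1 or more times, not at all. Squares are the sham array, circles joined by lines the paced arrays, dashed lines the 2-fold threshold, with 1 array per point. Pdk4 stood at 1.89 in sham, 3.54 at 0 h, 1.80 at 1 h and 1.70 at 24 h. Mt1 stood at 3.13 at 0 h, 0.47 at 1 h, 0.88 at 3 h, 3.16 at 8 h and 3.59 at 24 h.

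Across times, 4 genes met both conditions in the higher direction at 3 or more of the 5 times, Sik1, Lrrc58, Mt1 and Txnl1, and 3 genes did so in the lower direction, Plaat1, Aqp4 and Prkag3. Of these, Txnl1 and Aqp4 had 2 probes and the others 1. In 100 shuffles of the gene order of each paced array, with sham kept, the highest counts were 1 higher and 0 lower gene. The shuffles keep the shared sham values but not the shared Pre RNA. They also break the correlations between paced arrays, which had r from 0.53 to 0.75. An excess over the shuffles was therefore likely in advance, and it may come from Pre in part or in whole. Lrrc58 was the member that met both conditions at all times, with log2 differences from 1.10 at 8 h to 1.90 at 0 h. Sik1 differed from sham by 1.85 or more at each time, of which 1.03 came from its low sham value.

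**Figure D2:**
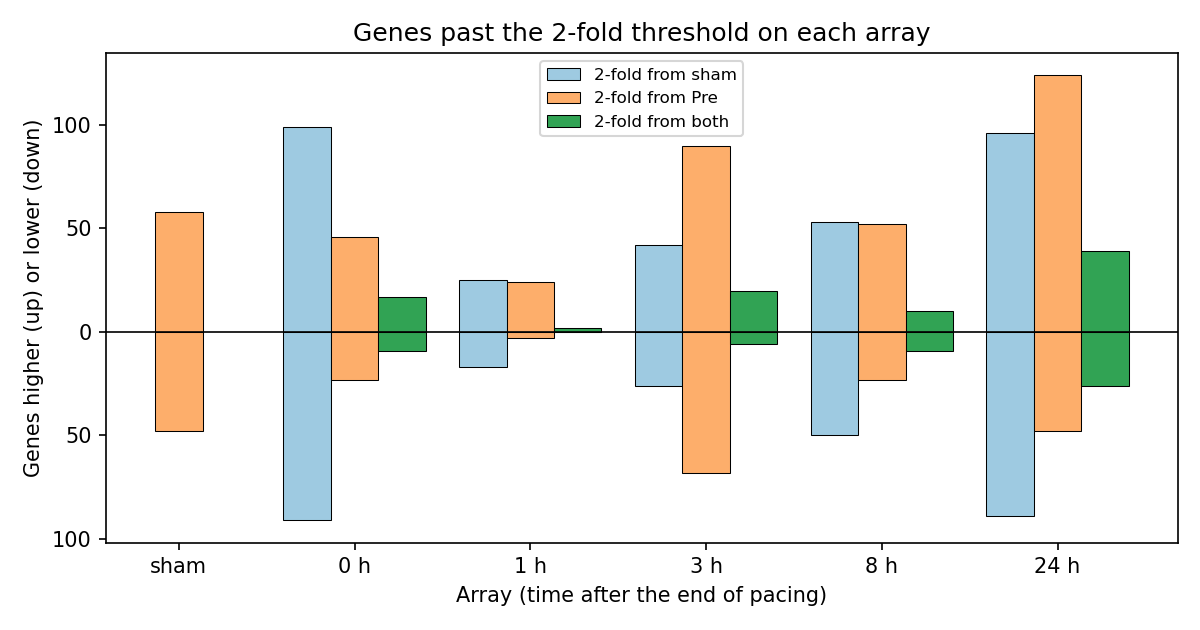
Number of genes (vertical axis; higher above 0, lower below) at least 2-fold from sham, from Pre, or from both, by array (horizontal axis), of 3180 genes with 1 array per group. The 24 h array had 39 higher and 26 lower genes that met both conditions and the 1 h array 2 and 0.

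**Figure D3:**
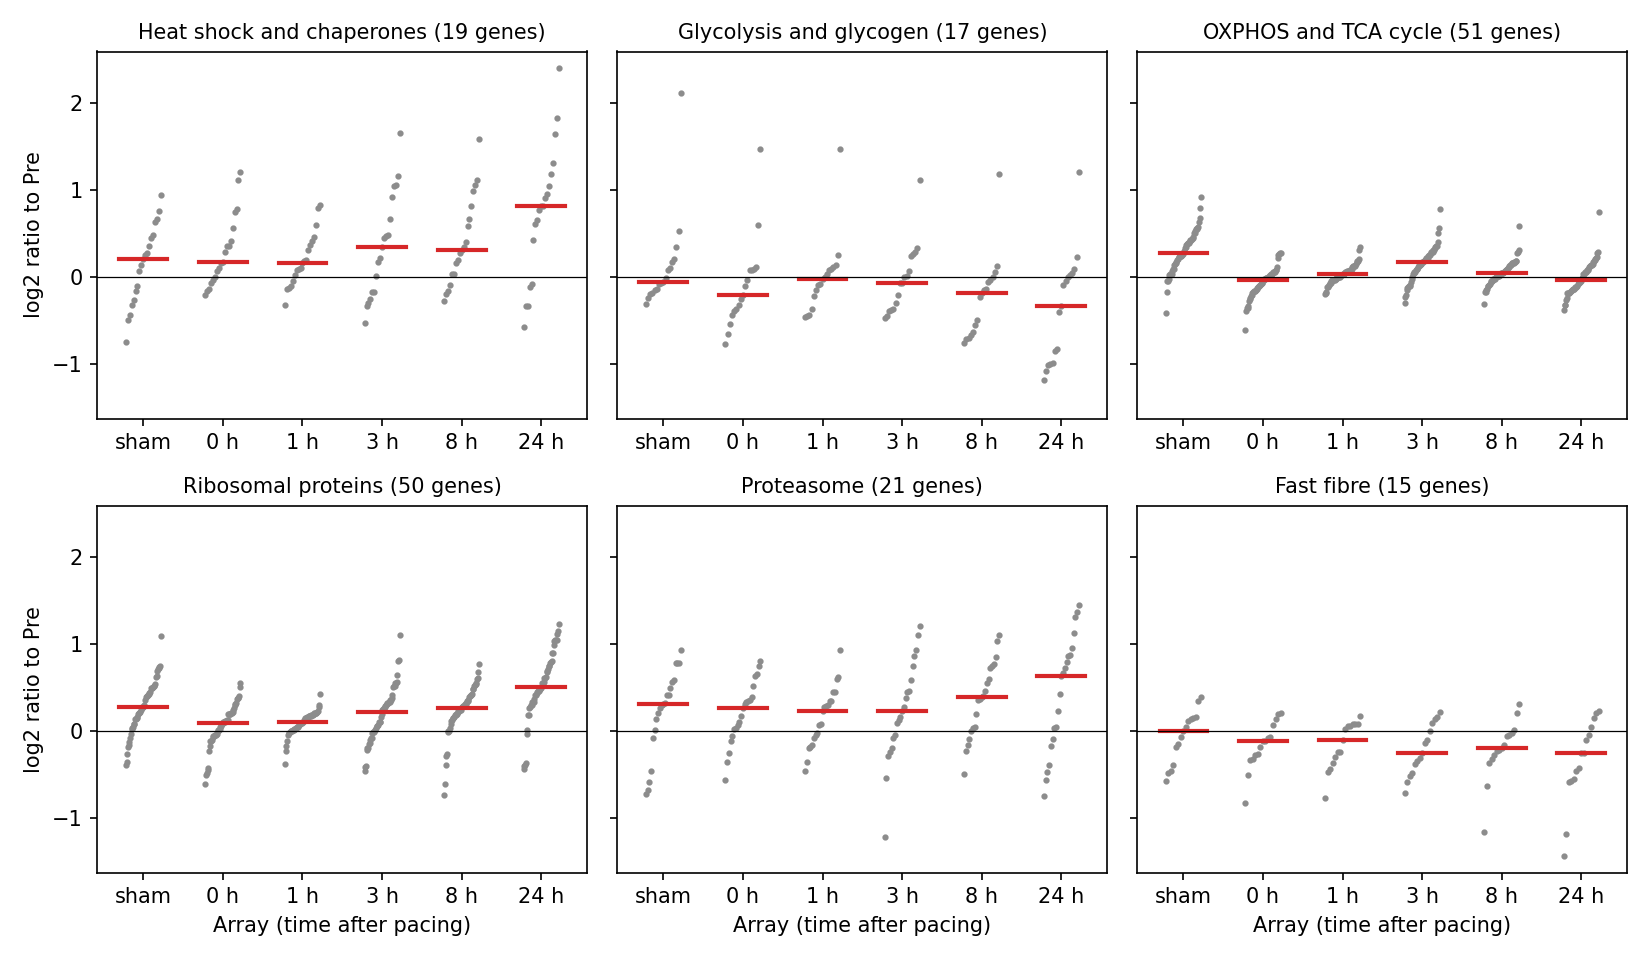
Log2 ratio to Pre (vertical axis) of each measured member of 6 gene lists (grey points, 1 gene each) and the list median (red line), by array (horizontal axis; 1 array each). Heat shock and chaperone genes had their highest median, 0.82, at 24 h, and oxidative phosphorylation and TCA cycle genes stood at 0.28 in sham and -0.03 at 24 h.

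Against sham, oxidative phosphorylation and TCA cycle genes had medians of -0.33 at 0 h, -0.26 at 1 h, -0.12 at 3 h, -0.21 at 8 h and -0.29 at 24 h. Against Pre the medians were -0.04, 0.03, 0.17, 0.05 and -0.03, so the position of this list depended on which unpaced RNA it was set against. None of its 51 members met both conditions at any time; Suclg1 at -1.25 (-1.64 on the 1 probe measured on both arrays), Uqcrb at -1.15 and Ndufa8 at -1.07 were lowest against sham at 0 h.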

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

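All tests below except the compression test of the 1 h array were chosen after the related values had been seen. The comparison at 3 h of genes called at 0 h or 8 h belongs to the later tests, because similar medians against Pre were known when its bounds were set.

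Probes without a single gene symbol were left out of the comparisons and drew attention because more of them were 2-fold from Pre on some paced arrays than on the sham array. Of 5045 such probes measured on all 6 arrays, 388 were 2-fold from Pre at 3 h and 318 at 24 h, against 302 in sham. The excess at 24 h over sham is small, and no test set it against chance.

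The 1 h array had small ratios, with a robust SD of 0.176 and 2 genes that met both conditions. If all its ratios were compressed, the 106 genes that were 2-fold from Pre in sham should also have been closer to 0 at 1 h than at 3 h, 8 h and 24 h; their signed median was 0.348 at 1 h, 0.275 at 8 h, 0.527 at 24 h and 0.918 at 3 h. The difference between 1 h and the lowest of these had a 95% bootstrap interval over genes from -0.033 to 0.149, which includes 0. If the transcripts had returned towards sham at 1 h, the genes that met both conditions at 24 h should have had the lowest scaled median there; it was 0.572, against 0.671 at 0 h and 0.498 at 3 h. Compression and a return towards sham cannot be told apart with 1 array per time.

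Mt1 and Fbxo32 were high at 0 h, 8 h and 24 h and near sham at 1 h and 3 h. Compression of both arrays is argued against for 3 h, where the robust SD was 0.445, above 0.292 at 0 h and 0.242 at 8 h. A 3 h array of unpaced muscle would leave the 33 other genes called at 0 h or 8 h near sham, with a signed median difference under 0.3 (their signed median in sham over Pre was -0.055); it was 0.647, with a 95% bootstrap interval over genes from 0.497 to 0.819. The bound set against a wrong label was 0.5, just above the interval's lower end. Across genes, the 3 h array correlated with sham (r = 0.654) more closely than any other paced array did. Its closest correlation was with the paced 1 h array (r = 0.715). All these ratios share the Pre RNA, so the correlations cannot decide the label, and a wrong label stays open. Mt1 was 2.28 log2 units higher at 8 h than at 3 h, and a course over time after pacing may account for that, but time and array cannot be told apart here. No sham array was matched to 3 h or 8 h, so elapsed time without pacing stays open as well.

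On all 6 arrays, 10 genes were at least 2-fold above Pre, Ei24, Fbxo32, Ifrd1, Pdk4, Ppp1r3c, Rgcc, Sel1l, Trim63, Ubb-ps and Vamp8, and 0 were lower. A low level of these 10 transcripts in the Pre RNA itself may give this, and so may the operation or harvest that sham and paced mice shared. The 106 genes 2-fold from Pre in sham kept a signed median of 0.348 as the middle value of the 5 paced arrays, from 0.135 at 0 h to 0.918 at 3 h. That value lies between the bounds set for the shared operation, and no array of another control RNA was measured. These explanations therefore cannot be told apart. Pre was in channel 2 on every array and the dyes are not stated, so an effect of the channel was not tested either.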

How the results depend on the processing

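Keeping zeros and shared values, keeping probes measured on both arrays, and the use of the double condition as a count were chosen after the data had been seen; the double condition itself was fixed before. Values as deposited and genes measured on the arrays compared moved none of the 11 counts by over 1.5 times. Pre in place of sham gave 69 genes at 0 h, 27 at 1 h and 158 at 3 h. Scaling the arrays to a common spread gave 28 for sham against Pre; 76 at 1 h, 26 at 3 h and 75 at 24 h against sham; and 67, 55, 9, 86 and 38 genes that met both conditions at 0 h, 1 h, 3 h, 8 h and 24 h. Probes counted one by one gave 519 for sham, then 852, 221, 352, 472 and 817 against sham and 108, 9, 134, 95 and 310 for both conditions in the same order of times; more features are counted there. The 1.5-fold threshold gave 590 for sham, 752, 353, 345, 559 and 703 against sham and 168, 15, 137, 84 and 274 for both. The threshold of 3 robust SDs of sham gave 24 for sham, 41, 7, 15, 16 and 36 against sham and 5, 1, 4, 3 and 17 for both. A looser or stricter threshold moves counts by construction. Zeros and shared values kept gave 164 for sham and 77 at 1 h. Probes measured on both arrays left 1 gene that met both conditions at 1 h, Lrrc58, since Retreg1 fell below the threshold.

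Among list medians outside the central 95% of the random lists, Pre in place of sham turned the sign of 6: oxidative phosphorylation and TCA cycle genes stood at 0.0306 at 1 h, 0.171 at 3 h and 0.0460 at 8 h, and ribosomal protein genes at 0.0978 at 0 h, 0.103 at 1 h and 0.222 at 3 h. The sham array itself lay above Pre for both lists, so the subtraction turns the sign. Scaling moved 23 of 95 list medians and 33 of 184 values of named genes by more than the pooled spread between probes of a gene, divided for lists by the square root of their size; the cause was not tested. The median of probes moved 4 of the 184, among them Ankrd1 at 24 h, from 3.01 to 4.10. The spread between arrays of 1 group is unknown, and no signal over background was given.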

Other observations

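Lists not described above had few measured members or medians near sham. The 13 antioxidant and metallothionein genes had medians from -0.10 at 0 h to 0.06 at 8 h against sham, with Mt1 the member that met both conditions. Against Pre the medians ran from 0.13 at 1 h to 0.25 at 24 h, and scaling to a common spread turned the 0 h median to 0.21. Hmox1, heme oxygenase, stood at -0.77 at 24 h against sham but at 0.02 against Pre, with sham at 0.79. Slow fibre genes had medians from -0.02 at 24 h to 0.19 at 0 h against sham; against Pre they stood at -0.06 at 0 h, -0.04 at 1 h, 0.02 at 3 h, 0.03 at 8 h and -0.25 at 24 h. Csrp3, a Z-disc protein, stood at 0.72 at 3 h against sham (8 probes, probe SD 0.62) and 0.32 against Pre. Extracellular matrix genes had medians from -0.04 at 24 h to 0.13 at 3 h against sham, but from -0.26 at 8 h to -0.09 at 1 h against Pre, and scaling turned the medians against sham to -0.13 at 0 h, -0.11 at 1 h and -0.12 at 8 h. In this list the largest differences from sham included Timp1, a protease inhibitor, at 0.89 at 0 h and Nid1 at -0.93 at 8 h. The 5 cytokine and acute phase genes had a median of 0.52 at 0 h and 0.43 at 8 h against sham (0.19 and 0.37 against Pre); Tgm2, a transglutaminase, stood at 1.41 at 24 h against sham and 0.95 against Pre. The 6 angiogenic and hypoxia genes had a median of -0.45 at 24 h against sham and -0.17 against Pre, the sham median itself lying at 0.32. Flt1, a vascular growth factor receptor gene, stood at -0.77 against sham and -0.25 against Pre.

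The 5 myogenic genes had a median of -0.27 at 8 h and 0.30 at 24 h against sham (-0.11 and -0.10 against Pre), and Mef2c, a muscle transcription factor, stood at -0.76 at 8 h. The 4 circadian genes had medians from -0.06 at 8 h to 0.21 at 0 h, the 5 interferon genes from -0.13 at 3 h to 0.02 at 8 h, and the 12 cell cycle genes from -0.08 at 24 h to 0.10 at 3 h. With arrays scaled to a common spread the signs of several of these small medians turned. The 15 exercise-responsive metabolic regulators had a median of -0.23 at 24 h, with 12 below sham, and -0.09 against Pre, with 9 below; the sham median was 0.33. Cpt1b, which carries fatty acids into mitochondria, stood at -1.03 against sham and -0.60 against Pre.

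No measured member of the 7 fixed marker lists of other cell types met both conditions. Few markers were measured, and from 2 (1 h) to 65 (24 h) of all 3180 genes met both conditions at a time. The absence therefore does not show that the cell types were unchanged. Pdgfra, a fibroblast receptor gene lower than both at 3 h, is on none of the lists. Macrophage and neutrophil markers, 5 measured, had medians from 0.03 at 24 h to 0.32 at 1 h against sham, whose own median was -0.21; against Pre they stood at 0.12 at 0 h, 0.01 at 1 h, -0.05 at 3 h, -0.03 at 8 h and -0.12 at 24 h. Endothelial and smooth muscle markers, 8 measured, had medians from -0.08 at 0 h to 0.08 at 8 h against sham and from -0.23 at 0 h to 0.02 at 3 h against Pre, with Myl9 at 1.42 at 0 h after a sham value of -1.18 against Pre. Adipocyte markers, 4 measured, had a median of -0.43 at 24 h against sham and -0.26 against Pre, with Car3 at -0.57 against sham, a gene that muscle also expresses. The 1 measured erythroid marker, Hba-a1, stood at -0.44 at 24 h, the lymphocyte marker H2-Eb1 at -0.26 at 24 h and the keratinocyte marker Perp at 0.65 at 0 h, all against sham (-0.31, -0.49 and 0.08 against Pre); 0 Schwann cell markers were measured.

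Among probes without a single gene symbol, probe 3452 stood at 3.84 and probe 7756 at -2.98 against sham at 24 h. Probe 9191 stood at 3.53 at 0 h and probe 8398 at -2.62.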
